A study of Anastrepha ludens with 9 samples.

How the data were processed

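RNA was measured in embryos of the Mexican fruit fly, Anastrepha ludens, at 3 stages of early development named syncytium, cellularization and gastrulation, with 3 libraries per stage. Groups, replicate numbers and collection windows in hours were taken from the sample labels. The series' design text calls the triplicates biological, and nothing in the sources used here says how many embryos or how many egg collections made up a library. RNA was extracted with TRI Reagent, per the labels' protocols, and the library kit, the strand setting and the read length are not given in the sources used here.

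Each library has a table with 1 row per assembled contig, holding its length, its effective length, an estimated count and a TPM value. The estimated counts and the TPM values were made by the authors with kallisto 0.44.4, per the submitters' processing notes and the deposited column names. FastQC 0.11.7 and MultiQC 1.5 are named in the same notes. The deposited estimated counts are not normalized and need not be whole, and they sum to between 28099549 and 51201882 per library. Estimated counts of 1000000 or more are written with 3 digits in the deposited tables, so the share of the most abundant contigs carries that rounding. The deposited TPM values sum to 1000000 in each library and are divided by the effective length, so they depend on the contigs of the assembly they were computed on. The deposited lengths and effective lengths are in bases. The contig names have the form that the assembler Trinity writes, with a part for the cluster, the component, the gene and the contig. The assembler's version and settings, any read trimming and the kallisto settings are not given in the sources used here.

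The 3 libraries of a stage list the same contigs with the same lengths, and the 3 stages list different assemblies of 78014, 114993 and 116309 contigs. A contig name that occurs in 2 stages was not taken to name the same sequence. Of 31463 names shared by syncytium and cellularization, 35 had the same length, against a mean of 28.4 and a 95% range of 19 to 38 when the lengths were shuffled 1000 times. Of 53991 names shared by cellularization and gastrulation, 116 had the same length, against a shuffled mean of 98.5 and a 95% range of 79 to 116. Of 32932 names shared by syncytium and gastrulation, 40 had the same length, against a shuffled mean of 29.8 and a 95% range of 20 to 42. Shared names did correlate across contigs between stages, with Spearman coefficients of 0.519, 0.473 and 0.528 for length and 0.220, 0.176 and 0.234 for TPM in the same order of pairs. Low cluster numbers go with long contigs in every assembly, with coefficients from -0.713 to -0.615. When values were shuffled 200 times only among names of the same suffix and neighbouring numbers, in blocks of 20 names, the correlations lay inside the shuffled 95% range in all 3 pairs. For length the shuffled means were 0.516, 0.469 and 0.529, against 0.519, 0.470 and 0.527 for the same names unshuffled, so the name itself added nothing detectable beyond its number. This check was added after the correlations were seen. The contig TRINITY_DN21648_c0_g1_i1, chosen as an example after its lengths were seen, has 913 bases in the syncytium, 743 at cellularization and 2070 at gastrulation. No sequences were used here with which contigs of different stages could be matched.

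For this reason the gene-level analysis that was fixed before the data were examined was not run. It comprised edgeR and DESeq2 tests of each gene between stages, the classes of genes by their course over the stages, the difference between the steps, the correlation of length with fold change and the tests of gene lists. None of the contig or gene names was found in the RefSeq gene table of assembly idAnaLude1.1, which holds 14586 protein-coding genes (0 matched). The lists fixed beforehand, of maternal, zygotic, segmentation, gastrulation, cell cycle, histone, ribosomal and cell type marker genes, are therefore void, and no gene symbol is given. The rule for named genes would have named the 10 largest rises and the 10 largest falls of each comparison, and allowed only a few bare names where no symbols are paired. It could not be applied, and the most abundant gene of each stage is named instead, chosen after its values were seen.

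Estimated counts and TPM of contigs were summed per Trinity gene, called an assembled gene here. A gene counted as detected at 1 TPM or more. Per library, the numbers of detected genes, the share of estimated counts in the 10, 100 and 1000 most abundant genes and the TPM-weighted median contig length were computed. Genes were also divided by their longest contig, at 1000 bases or more and under 500 bases, and by minimum levels of 10 and 100 TPM. Further measures were the number of genes that hold 50% of the counts, the effective number of genes (the exponential of the Shannon entropy of the count shares) and the number and shares of contigs per gene. The division by length, the higher levels and these further measures were chosen after the tables were seen.

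Each measure was compared over the 3 stages with an exact permutation test of the variance between stage means, over all 1680 ways to place the 9 libraries in 3 groups of 3, whose smallest p is 0.00357. Adjustment was by Benjamini and Hochberg over 21 measures. The test over the 3 stages was chosen after the planned gene-level tests proved impossible. Pairs of stages were compared, as planned, with two-sided exact permutation tests of the difference in means, which with 3 against 3 libraries cannot go below p = 0.1. The p-values cover the spread between the libraries of a stage and leave out what a second assembly of the same stage would change.

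Replicates were compared within each stage by Spearman correlation across genes with a mean of 5 TPM or more, and by the biological coefficient of variation, the square root of the common dispersion that edgeR 4.0.16 (R 4.3.3) estimates from estimated counts rounded to whole numbers, with TMM factors and the filterByExpr filter. The spread between the libraries of a stage was also divided into axes by singular value decomposition of log2(TPM + 0.5) over genes with a mean of 100 TPM or more. A chi-square comparison of counts over genes with 20 counts or more gave between 16.7 and 83.7 per degree of freedom for the pairs of replicates, so no pair agreed within sampling noise and each library was counted once. Other work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

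The measures were tested on simulated data. In libraries drawn from the real mean counts of each stage, with and without 200 genes raised 4-fold, the share of the 1000 most abundant genes was recovered within 0.00907 percentage points. These libraries differed by sampling noise only and used the stage's own assembly. The recovery therefore checks the calculation and bears neither on the spread between replicates nor on the difference between assemblies. A known coefficient of variation of 0.3 between simulated libraries was recovered as 0.294 for the syncytium, 0.295 for cellularization and 0.292 for gastrulation. With 200 genes raised 4-fold in 1 library it was recovered as 0.308, 0.309 and 0.305, a known 0.2 as 0.219, 0.219 and 0.218, and a known 0.1 as 0.141, 0.142 and 0.139. A few strongly changed genes therefore raise the estimate, and more so where the spread is small. Of simulated exact tests over 3 stages without an effect, 2% gave a p under 0.05.

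Alternatives were other minimum levels, a minimum count, thinning of every library to 28099467 counts, the smallest total after rounding, single contigs or larger groups of contigs in place of genes, TPM in place of counts for the shares, leaving out each library in turn, and exact tests that permute stages only within a replicate number.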

Results

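The transcriptome of Anastrepha ludens embryos was sequenced at 3 stages. Syncytium embryos (0 to 9 h) are at the stage in which nuclei divide without cell membranes between them, cellularization embryos (9 to 18 h) are at the stage in which membranes enclose the nuclei, and gastrulation embryos (18 to 30 h) are at the stage in which germ layers form. The design implies the comparison of each stage with the next and of gastrulation with the syncytium, and asks how the RNA content of the embryo changes over these steps. Each stage had 3 libraries. The syncytium libraries held 30588919, 29413974 and 51201882 estimated counts, the cellularization libraries 32599581, 33681067 and 29226591, and the gastrulation libraries 35455277, 28099549 and 37731673. The mean fragment length implied by the effective lengths was 159 ± 3.06 bases in the syncytium, 162 ± 2.19 at cellularization and 144 ± 2.92 at gastrulation (SD, n = 3 each).

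Reads of each stage had been assigned to an assembly of its own. The syncytium assembly comprised 78014 contigs in 45798 assembled genes, with a median contig of 845 bases. The cellularization assembly comprised 114993 contigs in 76713 genes, with a median of 473 bases, and the gastrulation assembly 116309 contigs in 75619 genes, with a median of 510 bases. Genes with a contig of 1000 bases or more were closer in number, at 14243, 15200 and 16031. Genes with no contig of 500 bases or more numbered 24845, 50850 and 48627. Contig names do not carry over between assemblies, so the stages were compared by the make-up of each RNA pool and not gene by gene. Stage and assembly cannot be told apart in any of these comparisons, because each stage has 1 assembly. The implied fragment length was also shorter at gastrulation than at both other stages, without overlap. It cannot be told apart from that stage either.

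Replicates of the syncytium were closest to each other. The Spearman correlation across genes between replicates ranged from 0.962 to 0.970 in the syncytium, from 0.892 to 0.952 at cellularization and from 0.935 to 0.960 at gastrulation. The coefficient of variation between replicates was 0.188 in the syncytium, 0.281 at cellularization and 0.234 at gastrulation by edgeR's common dispersion. It depends on how contigs are grouped, with 0.0937, 0.247 and 0.183 for contigs summed per component and 0.306, 0.379 and 0.355 for single contigs. Without cellularization replicate 3 the value for that stage was 0.222, below that of gastrulation.

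In the cellularization libraries, compared with the syncytium, more of the estimated counts fell on fewer assembled genes, each stage on its own assembly. The 1000 most abundant genes held 62.5% ± 1.81 of the counts at cellularization and 55.3% ± 0.226 in the syncytium (SD, n = 3 each). The 10 most abundant genes held 18.3% ± 1.70 and 13.4% ± 0.301, a difference of 4.91 percentage points that was 8.14 by TPM and 0.964 for the next 10 genes once these were removed. The number of genes that together held 50% of the counts was 441 ± 71.6 at cellularization and 729 ± 12.9 in the syncytium. Genes at 10 and at 100 TPM were also fewer, with 8284 ± 357 genes at 10 TPM or more against 9974 ± 55.7, and 1263 ± 123 genes at 100 TPM or more against 1579 ± 13.2. For each of these 5 measures all 3 cellularization libraries lay on one side of all 3 syncytium libraries, which gives an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. TPM sum to a fixed total in each library, so a larger share in the most abundant genes lowers the TPM of the rest. The 5 measures are therefore not independent of each other, here or in the comparisons below. Genes at 1000 TPM or more were not fewer, at 112 ± 5.86 and 107 ± 1.53, and the libraries overlapped (exact p = 0.2).

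Genes at low level showed the opposite direction. At 1 TPM or more, 36735 ± 6084 genes were detected at cellularization and 25776 ± 190 in the syncytium, a difference of 42.5% (exact p = 0.1, and 0.15 after adjustment over the 3 pairs of stages). By a minimum of 5 estimated counts the difference was 27.8% and the libraries overlapped (exact p = 0.2). The 3 cellularization libraries gave 37299, 42517 and 30388 genes. Genes whose longest contig was under 500 bases numbered 18984 ± 5111 against 9453 ± 144 and made up 87.0% of the additional genes. The assemblies list 50850 and 24845 such genes at any level, of which 37.3% and 38.0% were detected in the mean, and 76713 and 45798 genes in all. The number of short genes detected rose with the number listed, so a stage difference in low-level expression cannot be read from it. Genes with a contig of 1000 bases or more numbered 13161 ± 314 against 12846 ± 49.4, and the libraries of both stages overlapped (exact p = 0.3). Short genes between 1 and 10 TPM rested on a median of 3.85 estimated counts at cellularization and 4.58 in the syncytium, so their detection in a single library is close to the limit of the depth.

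**Figure D1:**
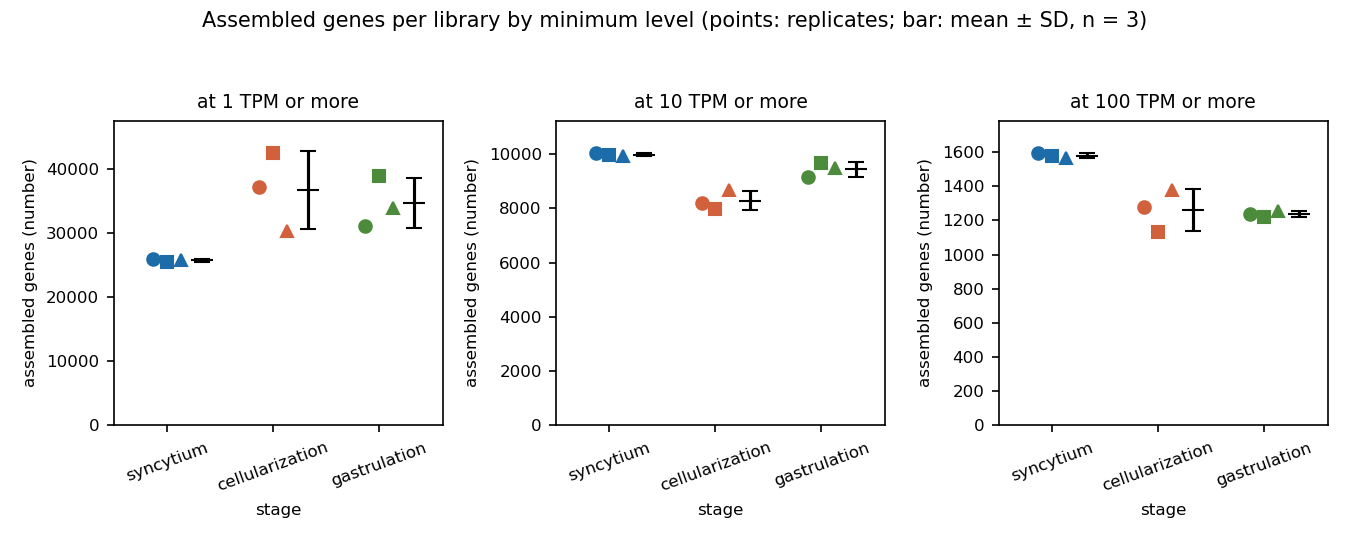
Number of assembled genes (vertical axes) in each library of the 3 stages (horizontal axes) at 1, 10 and 100 TPM or more. Circles, squares and triangles are replicates 1, 2 and 3 and bars are the mean ± SD (n = 3). Syncytium libraries are lowest at 1 TPM, between 25589 and 25968 genes, and highest at 10 TPM, between 9921 and 10032 genes.

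In the gastrulation libraries, compared with cellularization, counts were less concentrated in the most abundant genes and more genes reached 10 TPM. The 1000 most abundant genes held 56.1% ± 1.17 of the counts at gastrulation, against 62.5% at cellularization, a difference of -6.42 percentage points. The 10 most abundant genes held 13.4% ± 0.712 against 18.3%, and 680 ± 57.2 genes held 50% of the counts against 441. Genes at 10 TPM or more numbered 9432 ± 260 at gastrulation and 8284 at cellularization, 13.9% more. Genes with a contig of 1000 bases or more that reached 1 TPM numbered 13959 ± 364 against 13161, 6.06% more. For each of these 5 measures all 3 gastrulation libraries lay on one side of all 3 cellularization libraries (exact permutation p = 0.1, the smallest possible). The gastrulation assembly also lists more genes with a contig of 1000 bases or more at any level, 16031 against 15200. The number of genes at 1 TPM or more, 34711 ± 3955 against 36735 ± 6084, and at 100 TPM or more, 1238 ± 17.6 against 1263 ± 123, differed by less than the spread between replicates (exact p = 0.8 and 0.7). By TPM in place of counts, gastrulation differed from cellularization by -3.07 percentage points for the 1000 most abundant genes, without overlap, and by -2.17 for the 10 and -2.06 for the 100 most abundant, where the libraries overlapped (exact p = 0.2 and 0.3).

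**Figure D2:**
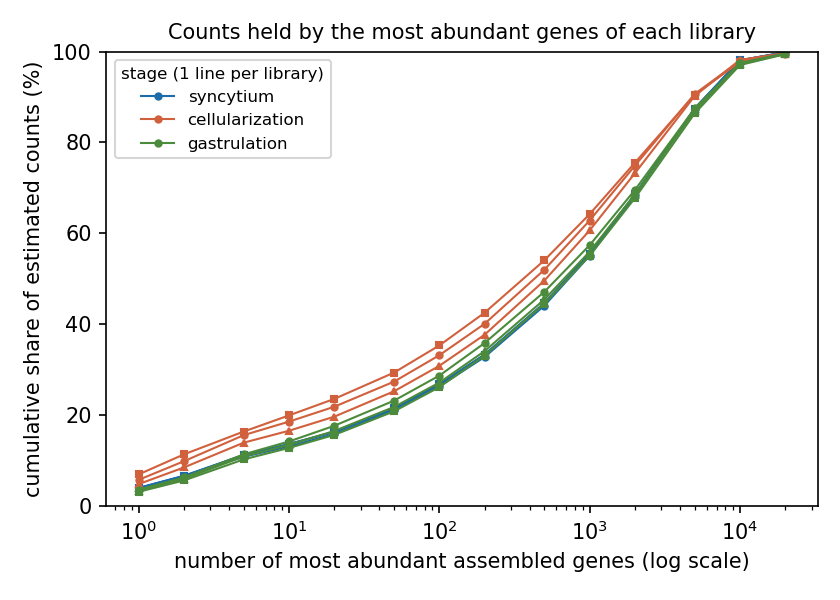
Cumulative share of estimated counts in percent (vertical axis) held by the most abundant assembled genes, by their number on a log scale (horizontal axis), with 1 line per library coloured by stage. At 1000 genes the cellularization libraries lie between 60.6% and 64.2%, above the syncytium libraries at 55.0% to 55.5% and the gastrulation libraries at 55.0% to 57.4%.

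In the gastrulation libraries, compared with the syncytium, counts were similarly concentrated but fewer genes reached 100 TPM. The share of the 1000 most abundant genes was 56.1% at gastrulation and 55.3% in the syncytium (exact p = 0.4; without overlap for contigs summed per component, by 0.985 percentage points, or per cluster, by 1.15), and that of the 10 most abundant was 13.4% in both (exact p = 1). Once the 10 most abundant genes were removed, the next 10 held 3.61% of the remaining counts at gastrulation and 3.12% in the syncytium. The next 100 held 17.0% and 16.1%, both without overlap (exact p = 0.1 each), while the next 1000 overlapped (exact p = 0.2). Genes at 100 TPM or more numbered 1238 ± 17.6 at gastrulation and 1579 ± 13.2 in the syncytium, a ratio of 0.784. Genes at 10 TPM or more numbered 9432 ± 260 and 9974 ± 55.7, a ratio of 0.946. More genes were detected at 1 TPM or more at gastrulation, by 34.7% among all genes and by 8.67% among genes with a contig of 1000 bases or more. In these last 4 counts the libraries of both stages did not overlap (exact permutation p = 0.1, the smallest possible). Genes at 1000 TPM or more went the other way from those at 10 and 100 TPM, at 114 ± 3.79 against 107 ± 1.53, also without overlap (exact p = 0.1). The gastrulation assembly lists 75619 genes against 45798, and 16031 against 14243 with a contig of 1000 bases or more. The excess at 1 TPM therefore cannot be told apart from the longer list. By TPM in place of counts, the 1000 most abundant genes held 62.6% ± 1.56 at gastrulation and 59.0% ± 0.464 in the syncytium, the 100 most abundant 37.3% ± 1.22 and 30.0% ± 0.356, and the 10 most abundant 18.8% ± 0.622 and 12.8% ± 0.170, without overlap in any of these (exact p = 0.1 each).

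Over the 3 stages together, most of these differences were larger than the spread between replicates. The exact permutation p was 0.00357 for genes at 10 TPM or more (0.025 after Benjamini-Hochberg adjustment over 21 measures), the smallest the design can give. It was 0.025 for genes at 100 TPM or more (adjusted 0.0404), 0.0143 for the share of the 1000 most abundant genes (adjusted 0.0333) and 0.0357 for the share of the 10 most abundant (adjusted 0.0469). It was 0.0107 for genes with a contig of 1000 bases or more at 1 TPM (adjusted 0.0281) and 0.0107 for the number of genes that hold 50% of the counts (adjusted 0.0281). The number of all genes at 1 TPM or more did not pass (exact p = 0.0607, adjusted 0.0708), nor did that of short genes after adjustment (exact p = 0.0464, adjusted 0.0574). Without cellularization replicate 3, the number of all genes at 1 TPM or more gave an exact p of 0.0107.

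**Figure D3:**
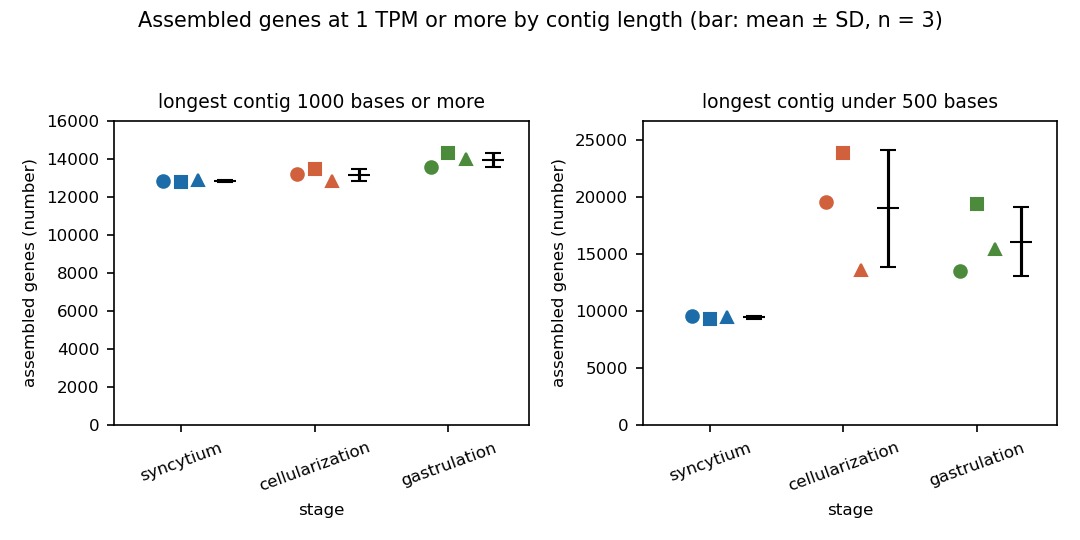
Number of assembled genes at 1 TPM or more (vertical axes) in each library of the 3 stages (horizontal axes), for genes with a contig of 1000 bases or more and for genes whose longest contig is under 500 bases. Circles, squares and triangles are replicates 1, 2 and 3 and bars are the mean ± SD (n = 3). Short genes lie between 13491 and 23816 in the later stages and between 9304 and 9592 in the syncytium, while long genes lie between 12792 and 14299 in all libraries.

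The most abundant assembled gene was the same in all 3 libraries of each stage. In the syncytium it was TRINITY_DN708_c0_g1, with 3.87% ± 0.0567 of the counts and a longest contig of 2686 bases. At cellularization it was TRINITY_DN11_c0_g1, with 5.78% ± 1.07 of the counts and a longest contig of 7921 bases, and at gastrulation TRINITY_DN145_c3_g1, with 3.29% ± 0.234 and 2779 bases (SD, n = 3 each). These genes were chosen after their values were seen, and no symbol is paired with them. Whether they are the same gene in different assemblies was not analysed here.

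Weighted by TPM, the median contig was shorter in the later stages than in the syncytium. The TPM-weighted median contig length was 1495 ± 31.5 bases in the syncytium, 1282 ± 96.5 at cellularization and 1257 ± 10.4 at gastrulation (SD, n = 3; exact p = 0.025, adjusted 0.0404). Contigs under 500 bases held 11.4% ± 0.0661, 17.0% ± 1.67 and 17.1% ± 0.647 of the TPM (exact p = 0.0321, adjusted 0.0469). Of the counts they held only 1.15% ± 0.0321, 1.94% ± 0.266 and 1.89% ± 0.0494. Genes at 1000 TPM or more with no contig of 500 bases or more, a few per library, held 5.09%, 7.22% and 8.56% of the TPM. The TPM shares therefore rest in part on a few short genes. Among genes at 100 TPM or more the median longest contig did not differ beyond the spread, at 1913, 1930 and 1933 bases (exact p = 0.875). Among the 100 most abundant genes by TPM it was longer in the later stages, at 1068 ± 10.3, 1275 ± 10.9 and 1302.5 ± 20.3 bases, with each later stage above the syncytium in all libraries (exact p = 0.1). Weighted by counts, which favour long contigs, the median was 2681 ± 47.1, 2558 ± 9.24 and 2738 ± 54.0 bases, so that gastrulation was no longer below the syncytium. Without syncytium replicate 1 the exact p of the TPM-weighted length was 0.0607.

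Genes at 10 TPM or more had several contigs in 63.5% ± 0.161 of cases in the syncytium, 67.6% ± 0.0621 at cellularization and 67.6% ± 0.290 at gastrulation (SD, n = 3; exact p = 0.0357, adjusted 0.0469). Contigs were counted as the stage's assembly lists them, with or without reads. The 3 libraries of a stage share that list and differ only in which genes reach 10 TPM. The SD and this p therefore cannot show a stage difference in contigs per gene apart from the assembly. In genes with several contigs, the leading contig held a median of 66.2%, 67.5% and 66.6% of the gene's TPM, which did not pass the test over the 3 stages (exact p = 0.0964, adjusted 0.101), although all cellularization libraries lay above all syncytium libraries (exact p = 0.1).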

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

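Levels of 10 and 100 TPM, the division by contig length, the minimum of 50 counts, components and clusters, removal of the 10 most abundant genes, other length measures, the settings of the replicate spread and the replicate block were chosen after the data were seen. Genes at cellularization against the syncytium, 42.5% more at 1 TPM, differed by 60.5% at 0.1 TPM, -7.57% at 5 TPM, -16.9% at 10 TPM, -20.0% at 100 TPM, 24.2% for single contigs, 2.45% for genes with a contig of 1000 bases or more, 101% for genes under 500 bases and -0.271% with 50 counts after thinning. For gastrulation against the syncytium, 34.7% at 1 TPM, the same settings gave 62.3%, -0.166%, -5.44%, -21.6%, 22.8%, 8.67%, 70.2% and 6.23%. With 5 estimated counts the first was 27.8%, with overlapping libraries, and the exact p over the stages 0.111. Gastrulation against cellularization, -5.51% with overlap, was 13.9% at 10 TPM, 8.01% at 5 TPM, 6.06% for genes with a contig of 1000 bases or more and 6.52% with 50 counts after thinning, all without overlap, and 4.59% with 5 counts, 3.32% with 5 counts after thinning, 1.10% at 0.1 TPM and 2.56% without cellularization replicate 2, with overlap. The exact p of 0.0607 over the stages became 0.0321 at 0.1 TPM, 0.0321 at 5 TPM, 0.00357 at 10 TPM, 0.025 at 100 TPM, 0.0107 for long genes, 0.0464 for short genes, 0.0429 with 5 and 0.025 with 50 counts after thinning. It ranged from 0.0107 (without cellularization replicate 3) to 0.143 on leaving out 1 library. By TPM, the shares of the 10 and 100 most abundant genes at cellularization lay 8.14 and 9.45 percentage points above the syncytium (4.91 and 6.52 by counts). Gastrulation against cellularization gave -2.17, -2.06 and, for 1000 genes, -3.07 points (-4.88, -5.79 and -6.42 by counts), with overlapping libraries for 10 and 100 genes, and gastrulation against the syncytium 5.96, 7.38 and 3.65 points (0.0255, 0.734 and 0.806 by counts), the last being 0.985 per component and 1.15 per cluster, without overlap. Without the 10 most abundant genes the first comparison gave 0.964, 3.03 and 5.77 points and the next -0.472, -2.13 and -4.85. Leaving out 1 library kept the exact p over the 3 stages under 0.05 for the shares of 10, 100 and 1000 genes. It could not change their direction at cellularization against the other stages, as libraries did not overlap. Their pairwise exact p cannot go below 0.1. The TPM-weighted contig length at cellularization against the syncytium, -14.3%, was -4.56% weighted by counts and 0.871% for the longest contig of genes at 100 TPM or more. At gastrulation it was -15.9% against the syncytium, and 2.15% and 1.04% by these measures, and against cellularization -1.92%, and 7.04% by counts. The exact p of 0.025 was 0.875 for the longest contig at 100 TPM or more, and from 0.00357 to 0.0607 (without syncytium replicate 1) on leaving out 1 library. The ratio of replicate spread at gastrulation over cellularization, 0.832, ranged from 0.678 to 1.05, the latter without cellularization replicate 3. With contigs summed per component, the ratio of cellularization over syncytium rose to 2.63 and that of gastrulation over syncytium from 1.25 to 1.96, as the syncytium's coefficient was 0.0937 in place of 0.188. The cause was not tested for any of these, beyond the weighing of genes at 1 TPM and of the 1000 most abundant genes in the next part. Replicate numbers were tried as a block by permuting stages only within a number, whose smallest p is 0.0278. The blocked exact p was 0.0833 for genes at 1 TPM, 0.111, 0.0833 and 0.0556 for the shares of 10, 100 and 1000 genes, and 0.0833 for the contig length. Whether the numbers pair libraries could not be checked, as names differ between stages. Of 285 alternatives to 23 results, 231 stayed within the spread between replicates, on the same side of 0.05 or, for ratios of replicate spread, within 1.5-fold. The gene-level tests' settings fixed beforehand (DESeq2, RLE, upper-quartile and total scaling, filters, single transcripts, fits of fewer libraries, the blocked fit, limma on TPM, the fold threshold of 2, camera and fry settings) and of the length correlation were not run, because no gene can be followed between stages. Short genes at 1 to 10 TPM rest on about 4 counts per library.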

Other observations

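All tests in this part were chosen after the result they bear on was seen, except the correlation with contig length, whose bounds were set first; thinning to 5 counts and the share over single contigs had been planned as alternatives. Genes at 1000 TPM or more numbered 107 ± 1.53 in the syncytium, 112 ± 5.86 at cellularization and 114 ± 3.79 at gastrulation (SD, n = 3). Among them, genes with no contig of 500 bases or more numbered 13.0 in each syncytium library, 12.0 ± 1.0 at cellularization and 9.33 ± 1.15 at gastrulation, and they held 5.09% ± 0.0409, 7.22% ± 0.699 and 8.56% ± 0.204 of the TPM. The number of genes that together held 90% of the counts was 5713 ± 14.6, 4855 ± 74.6 and 5896 ± 151. In exact permutation tests of pairs of stages, for which 0.1 is the smallest possible p, the share of TPM and the number of genes holding 90% of the counts gave 0.1 in all 3 pairs. The number of genes at 1000 TPM or more gave 0.1 between gastrulation and the syncytium, 0.2 between cellularization and the syncytium and 0.7 between the later stages. The number of short genes among them gave 0.1 for gastrulation against either other stage and 0.4 between cellularization and the syncytium.

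More genes reached 1 TPM at cellularization and gastrulation than in the syncytium. Counting depth went the other way: the syncytium libraries held a mean of 37068258 estimated counts, against 31835746 at cellularization and 33762166 at gastrulation. Syncytium replicate 3, at 51201882, raised the syncytium mean. Thinning to equal totals took most from the syncytium, so it could not be expected to lower the excess and cannot decide on depth. After it, 30.8% more genes had at least 5 counts at cellularization, and the libraries of both stages did not overlap. Whether depth acted through the number of contigs assembled was not tested, since the assemblies were fixed. Of the additional genes, 87.0% at cellularization and 74.3% at gastrulation had no contig of 500 bases or more, but so did 84.1% and 79.7% of the additional genes that the assemblies list at any level, so this share cannot decide whether short contigs of the later assemblies are the source. Of the listed genes with no contig of 500 bases or more, 37.3% and 33.1% were detected in the later stages and 38.0% in the syncytium. Whether more genes transcribed by gastrulation add to the excess cannot be decided from genes with a contig of 1000 bases or more. They were 8.67% more numerous at 1 TPM than in the syncytium, at 13959 against 12846, but the assemblies list 16031 against 14243 at any level. A fuller assembly would give the excess as well, so stage and assembly cannot be told apart for these genes.

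At cellularization a larger share of the counts lay in the 1000 most abundant genes. A few very abundant genes are not the whole cause, since without the 10 most abundant genes of each library the share was still 5.77 percentage points above the syncytium. The assembler's grouping of contigs into genes is argued against as well, because the difference was at least 6.76 percentage points over contigs, components and clusters, with no overlap between libraries. A change in the RNA pool between the stages, which the design names, stays open as untested, as does any other property of the 3 assemblies.

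The cellularization libraries differed mainly along 1 axis, which held 90.3% of the spread over 1266 genes at 100 TPM or more. The first axis held 82.1% at gastrulation and 56.1% in the syncytium. At a mean of 20 TPM or more it held 83.5%, 75.8% and 65.0% for the stages in this order. Simulated libraries with independent spread of equal size gave 52.2%. Independent spread of unequal size was not simulated, so 52.2% cannot tell a common course from larger spread in some libraries. Replicate 1 lay between replicates 2 and 3 on this first axis, with scores of -0.09, -0.66 and 0.75. The same libraries detected 19503, 23816 and 13633 short genes. They held 32599581, 33681067 and 29226591 estimated counts, with implied mean fragment lengths of 162.1, 160.3 and 164.6 bases. Reads were assigned to 83.3%, 86.9% and 73.6% of the contigs. All of these measures also placed replicate 1 between replicates 2 and 3. Among 3 libraries 1 always lies between the others, so the scores do not exclude a single deviating library. Without replicate 3 the coefficient of variation fell from 0.281 to 0.222, and without replicate 2 to 0.264. Division of reads among contigs of the same cluster is argued against as the main source. The log2 SD between the cellularization libraries was 0.254 per gene and 0.230 with contigs summed per cluster. The latter lay above the 0.09 of the syncytium genes and the 0.075 of the syncytium clusters. Related genes in separate clusters were not pooled, so division of reads among those was not tested. A length bias stays open, because across genes, which are not independent replicates, the log2 ratio of replicate 3 to replicate 2 correlated with the longest contig at a Spearman rho of 0.230, between the bounds of 0.1 and 0.3 set beforehand. Embryos of different age within the collection window could give such an axis too, as could another graded difference between libraries. Depth and fragment length differed in the same order as the scores, and whether they give the axis was not tested. With 3 libraries and no gene symbols these causes cannot be told apart.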
